A study of Mus musculus with 11 samples.

How the data were processed

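The samples were 11 poly(A) RNA libraries of SMB21, a line from a medulloblastoma of Ptch1-mutant mice that is grown as neurospheres. Per the labels, the libraries were stranded, made from 500 ng of RNA and read from 1 end at 75 bp on a single instrument run. They were grouped by the labels into untreated parental cells (n = 3), parental cells after 24 h with sonidegib (n = 2), Sufu-mutant clones (n = 2) and Ofd1-mutant clones (n = 4). The Sufu libraries came from clones R13 (replicate 1) and R1 (replicate 2). The 4 Ofd1 libraries came from 3 clones, with clone R14 as replicates 1 and 2, R16 as replicate 3 and R25 as replicate 4. The clones came from a screen for drug resistance, and the labels do not state whether they were grown with drug.

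The authors provided 1 table of raw counts of reads per gene symbol, with 1 column per library. Their notes name STAR, DESeq2 and genome build mm9, and the counting tool, the gene annotation and the versions are not given in the sources used here. The values were checked to be whole numbers of at least 0. The table held 22620 entries. One of them named no gene, took 0.0131% to 0.0192% of the counts of a library and was left out, which left 22619 genes. No mitochondrial gene was in the table, so the list of mitochondrial transcripts was not used here. Totals per library ran from 24308451 to 38241595 counts. Reads without molecular identifiers are not independent molecules, so limits for a count of 0, set at 3 counts over a group, cover counting error only.

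Groups were compared pairwise with the edgeR quasi-likelihood test (edgeR 4.0.16 in R 4.3.3, robust fit, TMM factors), on the libraries of the groups compared and on genes kept by filterByExpr. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05, and tests were two-sided. Levels are CPM of the TMM-scaled library size, given as mean ± SD. Log2 fold changes carry a standard error taken from the fold change and the F statistic. The comparisons were sonidegib, Sufu mutant and Ofd1 mutant each against untreated parental cells, and Ofd1 against Sufu mutant. Both clone classes were also compared with sonidegib-treated cells. Clones or cultures were the replicates, except that clone R14 gave a pair of libraries.

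The lists, 28 in all with 679 entries of which 666 were in the table, were fixed before the data were examined. They cover Hedgehog targets, a 4-gene core of that list, Hedgehog coreceptors, other Hedgehog machinery, cilia, S phase, G2/M phase, granule cell progenitors, neuronal differentiation, neural stem cells, astrocytes, oligodendrocytes, microglia and macrophages, fibroblasts and pericytes, and endothelium. The others cover MAPK output, TGF-beta and BMP targets, Wnt targets, Notch targets, p53 targets, cholesterol synthesis, the integrated stress response, hypoxia and glycolysis, interferon response, matrix and adhesion, replication histones, drug efflux transporters and mitochondrial transcripts. Each list was tested with camera (limma 3.58.1) at a preset correlation of 0.01 and adjusted over the lists of a comparison. The test was repeated with an estimated correlation. The coreceptors were listed as genes that Hedgehog signalling represses.

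Genes were named by a rule set before the data were examined. It took up to 12 rises and 12 falls with the largest fold change among genes with adjusted p under 0.05, an absolute log2 fold change of 1 or more, a mean of at least 5 CPM and no overlap between the groups. Clone-type and predicted-gene symbols were passed over. Ofd1, Sufu and detected Hedgehog targets were named in any case, and up to 4 members that passed the test were taken from each called list. Other members of a list are given as examples, and these were chosen after their values were seen. Some genes that these rules name are not reported here.

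The drug response was carried over to the clones as the set of genes called lower after sonidegib with a log2 fold change of -1 or less, tested with camera in Ofd1 against Sufu libraries, which did not define it. Correlations of fold changes across genes that share the parental controls were set against 20 simulations in which the treated groups did not differ from those controls. Transcript length was taken by symbol from GENCODE M21 (GRCm38) for 14193 of 14306 genes, 99.2%. Chromosome and order along it were taken from the same annotation. That annotation is not the build the reads were aligned to, so no positions are given. Median shifts per chromosome used 10864 genes with a mean of at least 5 CPM, against the median of all libraries for each gene and with the trend of each library on transcript length removed, and were set against 1000 permutations of the chromosome labels.

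The procedure was tested on simulated data with 10 draws per comparison. A shifted list was called in 10 of 10 draws and an unchanged list in 0 of 10, in each comparison. Simulated genes varied independently, so these draws do not test list calls where the genes of a list vary together. The estimated correlation was 0.401 for S phase and 0.449 for G2/M genes after sonidegib. Among genes called, false calls made up a mean of 9.20% for sonidegib, 6.75% for Sufu and 6.24% for Ofd1 against parental cells, 6.74% for Ofd1 against Sufu, 9.41% for Sufu and 6.96% for Ofd1 against sonidegib, above the nominal 5%. For 4-fold changes the tests recovered 69.3%, 74.6%, 85.3%, 73.1%, 48.4% and 72.4% of genes in the same order. For 2-fold changes they recovered 10.2%, 27.0%, 56.1%, 31.8%, 3.25% and 16.7%.

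The alternatives were DESeq2 size factors, no filter on low counts, the DESeq2 1.42.0 Wald test, all 11 libraries in a single fit, each library left out in turn, R14 libraries summed, and replicate number as a block. The replicate numbers did not pair the libraries. Removing each library's length trend, and repeating comparisons inside the sets of libraries that lay together on a principal component, were chosen after seeing the data. Those sets were parental replicates 1 and 2 with sonidegib replicate 1, called the first set, and parental replicate 3 as the control for the clones, called the second set. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.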

Results

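Poly(A) RNA levels were measured in 11 libraries of SMB21 medulloblastoma cells. There were 3 libraries of untreated parental cells, 2 of parental cells kept for 24 h in sonidegib, an inhibitor of the Hedgehog signal transducer Smoothened, 2 of Sufu-mutant clones and 4 of Ofd1-mutant clones. Total counts were 32376390, 38241595 and 33493975 in parental replicates 1, 2 and 3, and 29294858 and 34419880 in sonidegib replicates 1 and 2. The Sufu-mutant libraries held 24308451 counts for clone R13 and 24433265 for R1. The Ofd1-mutant libraries held 31775081 and 32561656 for clone R14, 30853655 for R16 and 37457641 for R25.

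The transcripts of the mutated genes were lower in their clones but still present. Ofd1, which codes for a protein of the centriole and the base of the cilium, stood at 15.0 ± 5.99 CPM (SD, n = 4) in the Ofd1 mutants and at 38.5 ± 3.95 CPM (n = 3) in parental cells, a log2 difference of -1.35 ± 0.28 (SE) with an adjusted p of 0.0853. The 4 libraries held 13.6, 23.4, 9.27 and 13.6 CPM. Sufu, a suppressor of Gli transcription factors, stood at 2.76 CPM in clone R13 and 17.7 CPM in clone R1, against 29.6, 27.7 and 28.7 CPM in parental replicates 1, 2 and 3. Its log2 difference in the Sufu mutants was -1.47 ± 0.69, with an adjusted p of 0.563. Sufu was also at 14.8 ± 3.32 CPM (n = 4) in the Ofd1 mutants, a log2 difference of -0.94 ± 0.19 with an adjusted p of 0.0790. The difference of neither gene passed the test over all genes in its own clones.

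Sonidegib against untreated parental cells shows what 24 h of Smoothened inhibition did to the transcripts of the parental line. Hedgehog target genes and cell cycle genes were lower. Gli1, the transcription factor at the end of the pathway and itself a target, fell from 229 ± 12.3 CPM (n = 3) to 8.25 ± 0.809 CPM (n = 2), a log2 change of -4.80 ± 0.24. The Hedgehog-binding protein Hhip fell by 3.51 ± 0.29 on the log2 scale. Sorcs2, a sortilin-family receptor, changed by -3.07, Plxna2, a semaphorin receptor, by -2.27, the replication licensing factor Cdc6 by -2.12 and the exonuclease Exo1 by -1.95. Igfbp5, which binds insulin-like growth factors, rose from 102 ± 13.3 to 765 ± 123 CPM, a log2 change of 2.91 ± 0.23. In all, 9 of 13809 genes changed, 1 higher and 8 lower, with adjusted p from 0.00287 to 0.0411.

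As groups, 13 detected Hedgehog targets had a median log2 change of -1.68 after sonidegib (camera adjusted p = 6.09e-19, 0.0950 with an estimated correlation). Of these, 3 fell over all genes tested. Adjusted over the list alone, 7 fell, among them the cyclin gene Ccnd1 at -1.68, the survival gene Bcl2 at -1.32, Cdk6 at -2.02 and Prdm1 at -2.61, and 1 rose, the granule cell progenitor factor Atoh1 at 0.83 ± 0.25. Cdk6 stood at 26.9 CPM in sonidegib replicate 1 and 7.03 CPM in replicate 2, and its log2 change was -3.34 without the former and -1.37 without the latter. Without sonidegib replicate 1 Prdm1 was at -3.26. Mycn at 0.35, Ccnd2 at -0.13 (-0.74 without sonidegib replicate 1), Sfrp1 at -0.75, Igf2 at -0.07 and Ptch1 passed neither test. Ptch1 stood at 37.5 CPM in sonidegib replicate 1 and 1.19 CPM in replicate 2, against 77.7 ± 10.7 CPM in parental cells (adjusted p = 0.435). The core of 4 targets had a median of -3.52 (adjusted p = 4.01e-30, and 0.0354 with an estimated correlation). The plot of Hedgehog gene levels shows Gli1, Ptch1, Hhip, Ccnd1, Bcl2 and Atoh1 in every library.

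**Figure D1:**
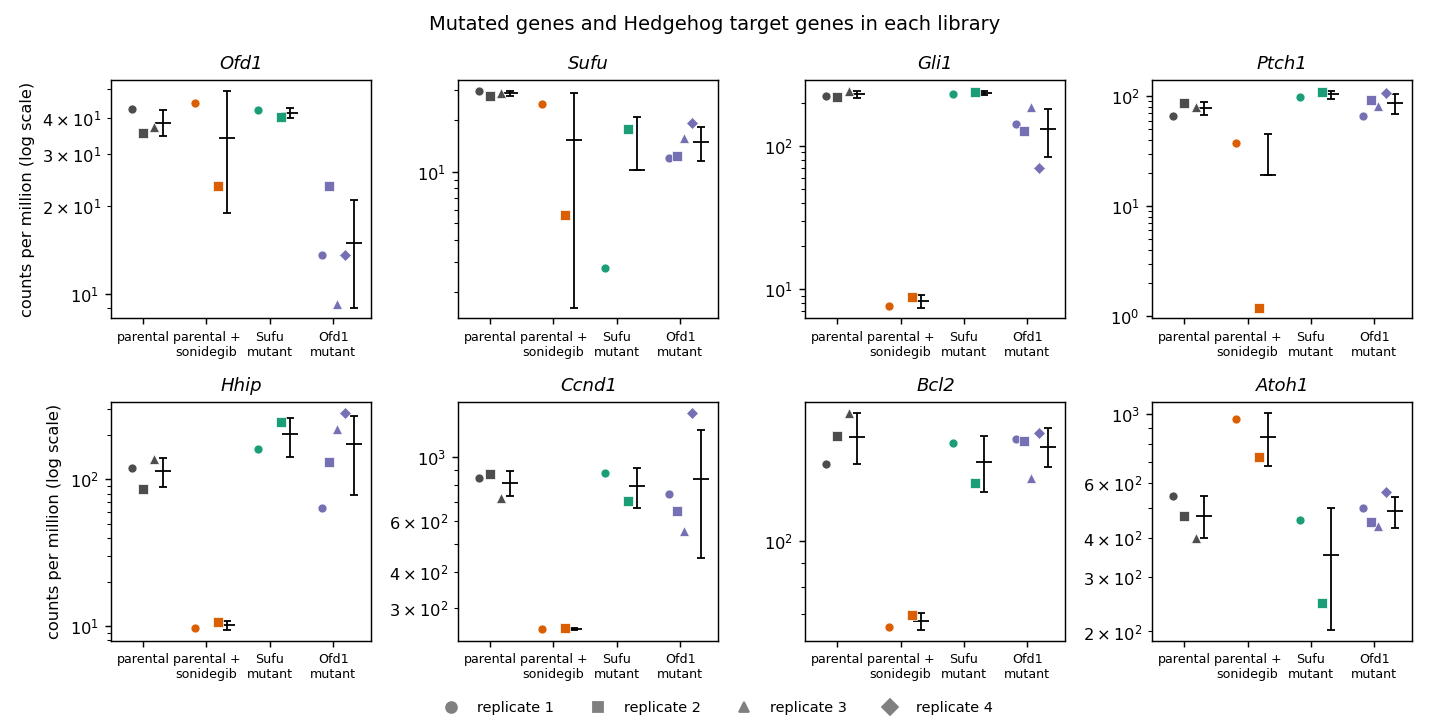
CPM (log axis) of Ofd1, Sufu, Gli1, Ptch1, Hhip, Ccnd1, Bcl2 and Atoh1 in each of the 11 libraries by group, with the symbol giving the replicate and the black mark the mean with its SD; the lower bar is left out where the SD exceeds the mean, as for Ptch1 after sonidegib and Sufu in the Sufu mutants. Gli1 lies at 7.68 and 8.82 CPM after sonidegib and at 69.9 or more in every other library.

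All 43 S phase genes had a negative log2 change after sonidegib, with a median of -1.19 (adjusted p = 3.42e-45, and 0.241 with an estimated correlation). Cdc6 and Exo1 fell over all genes, and 35 fell when adjusted over the list alone. All 52 G2/M genes were also negative, with a median of -1.09 (adjusted p = 5.44e-35, and 0.273 with an estimated correlation), and 41 fell when adjusted over the list alone. The proliferation marker Mki67 stood at 185 ± 105 against 724 ± 66.2 CPM, and the topoisomerase Top2a at 213 ± 95.3 against 826 ± 78.6 CPM. Both sonidegib libraries lay below all 3 parental libraries for 39 S phase and 46 G2/M genes, where chance separates 20% of genes in either direction.

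Further groups were called by camera in sonidegib-treated cells. MAPK output genes were lower (median -0.72, adjusted p = 7.76e-06), with Spry4, an inhibitor of receptor tyrosine kinase signalling, at 4.12 ± 1.82 against 16.9 ± 3.01 CPM and Dusp6, a phosphatase for ERK, at a log2 difference of -2.22. Stress response genes (median -0.65, adjusted p = 2.35e-06), Wnt targets (median -0.75, adjusted p = 3.65e-04) and the coreceptors Gas1, Boc and Cdon (median -1.23, adjusted p = 0.0144) were lower as well. The coreceptors were listed as repressed by Hedgehog signalling, so a fall with the inhibitor is opposite to that listing. The Wnt list shares Ccnd1 and Sfrp1 with the Hedgehog targets, and its median is the value of Sfrp1. Granule progenitor genes were higher (median 0.26, adjusted p = 4.64e-04), with Barhl1, a cerebellar homeobox factor, at 1069.9 ± 216 against 470 ± 89.2 CPM and Nhlh1 at 537 ± 96.7 against 253 ± 85.8 CPM. Of these 5 lists none passed with an estimated correlation (adjusted p = 0.258 to 0.513). Over the list alone, 6 MAPK, 3 stress, 1 Wnt and 2 coreceptor genes fell and 6 granule progenitor genes rose. Without sonidegib replicate 1 the stress, Wnt, coreceptor and progenitor calls were lost, with adjusted p of 0.169, 0.0685, 0.371 and 0.155.

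The remaining lists did not pass the test over all 5 libraries after sonidegib. Neuronal differentiation genes had a median of 0.41 (adjusted p = 0.157), cilia genes 0.15 (0.159), cholesterol synthesis -0.32 (0.0612) and matrix and adhesion -0.25 (0.0936). With parental replicates 1 and 2 and sonidegib replicate 1 alone, the medians were -0.50 for cholesterol synthesis, 0.31 for neuronal differentiation and -0.13 for Notch targets. With 1 treated library no p is given for these. Markers of astrocytes (median 0.19), oligodendrocytes (-0.61), fibroblasts and pericytes (-0.81), endothelium (-0.32) and the 1 detected microglial gene (0.64) had adjusted p from 0.239 to 0.707. Other Hedgehog machinery, neural stem, TGF-beta and BMP, Notch, p53, hypoxia and glycolysis, interferon, replication histone and drug efflux lists had adjusted p from 0.278 to 0.997.

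The number of genes called rested on single libraries. It was 0 without parental replicate 3, 1 without parental replicate 1 or sonidegib replicate 2, 2 without parental replicate 2 and 3263 without sonidegib replicate 1, while the DESeq2 test called 707, 210 higher and 497 lower. Sonidegib replicate 2 had less signal from long transcripts than any other library, with a correlation of its levels with transcript length of -0.491 against -0.0145 to 0.207 in the others. On the second principal component, 17.5% of variance, parental replicates 1 and 2 and sonidegib replicate 1 lay at 43.0 to 46.5 and the other 8 libraries at -53.4 to -3.58. Inside that first set, which holds 1 sonidegib library, the S phase median was -1.48, the G2/M median -1.06 and the Hedgehog median -1.28. No result is read from the count of changed genes in that set, which appears below only among the processing alternatives. The reason is that its spread comes from parental replicates 1 and 2 alone. These replicates differed across genes by an SD of 0.376 (log2), against 1.01 between the sonidegib libraries.

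Sufu-mutant clones against parental cells shows how clones with this lesion differ from the line they came from. Gli1 was at 234 ± 6.75 CPM (n = 2) against 229 ± 12.3 CPM (n = 3), a log2 difference of 0.04 ± 0.13. Hhip at 0.84, Prdm1 at 1.65, Igf2 at 1.00, Ptch1 at 0.43, Sfrp1 at 0.27, Ccnd2 at 0.16, Ccnd1 at -0.02, Cdk6 at -0.03, Bcl2 at -0.16, Mycn at -0.31 and Atoh1 at -0.41 did not pass. Without clone R13 Igf2 was at -0.34 and Sfrp1 at -0.71, and without R1 Igf2 was at 1.68. Over all 13854 genes, 0 changed by edgeR, with 1341 at an unadjusted p under 0.05, and the DESeq2 test called 324, 143 higher and 181 lower. Without parental replicate 3 edgeR called 11.

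Among the groups in Sufu mutants, Hedgehog targets were higher (median 0.16, adjusted p = 0.0175), as were the core of 4 (median 0.63, adjusted p = 3.13e-05) and the coreceptors (median 0.65, adjusted p = 0.0175). For the coreceptors, listed as repressed by Hedgehog signalling, a rise beside higher targets is opposite to that listing. MAPK output was higher (median 0.40, adjusted p = 1.76e-07), with the early response gene Egr1 at 54.9 ± 0.492 against 14.4 ± 2.44 CPM, Spry4 at 56.6 ± 13.9 against 16.9 ± 3.01 CPM, and 4 genes higher when adjusted over the list alone. Stress response genes were higher (median 0.56, adjusted p = 3.13e-05), and this rested on clone R1, since the median was -0.12 without it. Oligodendrocyte markers were higher (median 0.30, adjusted p = 0.0135), with the lineage factor Olig2 at 2.99 ± 0.882 against 0.496 ± 0.0410 CPM and 2 genes higher over the list alone. None of these passed with an estimated correlation (adjusted p = 0.404 to 0.602). The Hedgehog call was lost without parental replicate 1 (adjusted p = 0.0575), parental replicate 3 (0.0501) or clone R13 (0.408). The coreceptor and oligodendrocyte calls were lost without parental replicate 1 (0.0853 and 0.0907), parental replicate 2 (0.0600 and 0.139) or clone R1 (0.106 and 0.0925), and the coreceptor call also without R13 (0.117). With parental replicate 3 as the only control the Hedgehog, coreceptor, stress and oligodendrocyte calls were lost, at medians of 0.14, 0.54, 0.38 and 0.12. With 1 control library no p is given for these.

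Other groups were lower in the Sufu mutants. Neural stem genes had a median of -0.34 (adjusted p = 0.00443), with the stem cell factor Sox2 at 11.7 ± 1.49 against 30.0 ± 5.72 CPM. S phase genes had a median of -0.21 (adjusted p = 3.13e-05), cholesterol synthesis -0.25 (6.26e-04), granule progenitor genes -0.32 (0.0135) and cilia genes -0.15 (0.00489). None passed with an estimated correlation (adjusted p = 0.404 to 0.638). With parental replicate 3 as the only control, all 5 calls were lost. The medians there were 0.04 for cilia, 0.09 for granule progenitor, -0.03 for S phase, 0.0014 for cholesterol and -0.14 for neural stem genes. G2/M genes had a median of 0.20 there. With 1 control library no p is given for these. The calls for cilia and progenitor genes were also lost without parental replicate 1 (adjusted p = 0.0648 for both) or 2 (0.0600 and 0.0646). Without R1 the cilia call was lost (0.133), and without R13 those for progenitor and cholesterol genes (0.305 for both). G2/M genes (median -0.08, adjusted p = 0.104), other Hedgehog machinery (-0.17, 0.0539), p53 targets (0.12, 0.0877), astrocyte markers (-0.22, 0.216), the microglial gene (0.79, 0.337), fibroblast and pericyte markers (0.18, 0.508) and endothelial markers (-0.12, with a mean of 0.06 and a test that pointed upward, 0.656) did not pass. Nor did neuronal differentiation, TGF-beta and BMP, Wnt, Notch, hypoxia and glycolysis, interferon, matrix, replication histone and drug efflux lists (adjusted p = 0.456 to 0.976).

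Ofd1-mutant clones against parental cells asks the same of the other class of clones. Of 13779 genes, 50 changed, 25 higher and 25 lower. Col18a1, which codes for a basement membrane collagen, rose from 3.81 ± 0.959 CPM (n = 3) to 83.8 ± 41.8 CPM (n = 4), a log2 change of 4.46 ± 0.47. Ucp2, a mitochondrial carrier, rose by 4.57 ± 0.63 and the LIM protein gene Fhl1 by 4.29 ± 0.65. The rises of Lonrf3, Thy1, Slc26a10, Tceal1, Fbn2, Hrh1, Dync1i1, Syt1 and Wwc2 ran from 1.82 to 2.82. Both Sufu clones also lay above every untreated parental library for Col18a1, Fhl1, Lonrf3, Tceal1, Fbn2 and Hrh1, but not for the other named rises. Chance separates 20% of genes in either direction for 2 against 3 libraries, and the same parental libraries chose these genes. Col18a1 was at 4.79 CPM in R1 against 4.75 in parental replicate 2, and at 5.74 and 11.2 CPM in sonidegib replicates 1 and 2. Tceal1 was at 1.89 CPM in R1 against 1.71 in parental replicate 1. Syt1, the calcium sensor of synaptic vesicles, went from 36.8 ± 1.31 to 144 ± 57.4 CPM.

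Among the falls in Ofd1 mutants, the secreted Wnt ligand Wnt5a changed by -2.02 ± 0.25 on the log2 scale. Tcf7l2, a transcription factor of Wnt signalling, went from 14.2 ± 3.02 to 4.46 ± 0.971 CPM, a log2 change of -1.66 ± 0.24. The matrix glycoprotein gene Emilin1 changed by -2.09, the neurofilament gene Ina by -1.45, the actin-associated Afap1 by -1.14 and the ribosomal protein gene Rpl41 by -1.01. Rpl41 stood at 362 ± 29.0 against 734 ± 72.5 CPM, and at 2308 CPM in sonidegib replicate 2, the library with less signal from long transcripts. Both Sufu clones also lay below every untreated parental library for Emilin1, Wnt5a, Tcf7l2, Afap1 and Rpl41, but not for Ina. These falls too were chosen on the same parental libraries. Tcf7l2 was at 3.93 CPM in R13 and 6.26 CPM in R1. Wnt5a was at 62.7, 60.9 and 32.4 CPM in parental replicates 1, 2 and 3. The plot of genes named for the Ofd1 mutants shows each library.

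**Figure D2:**
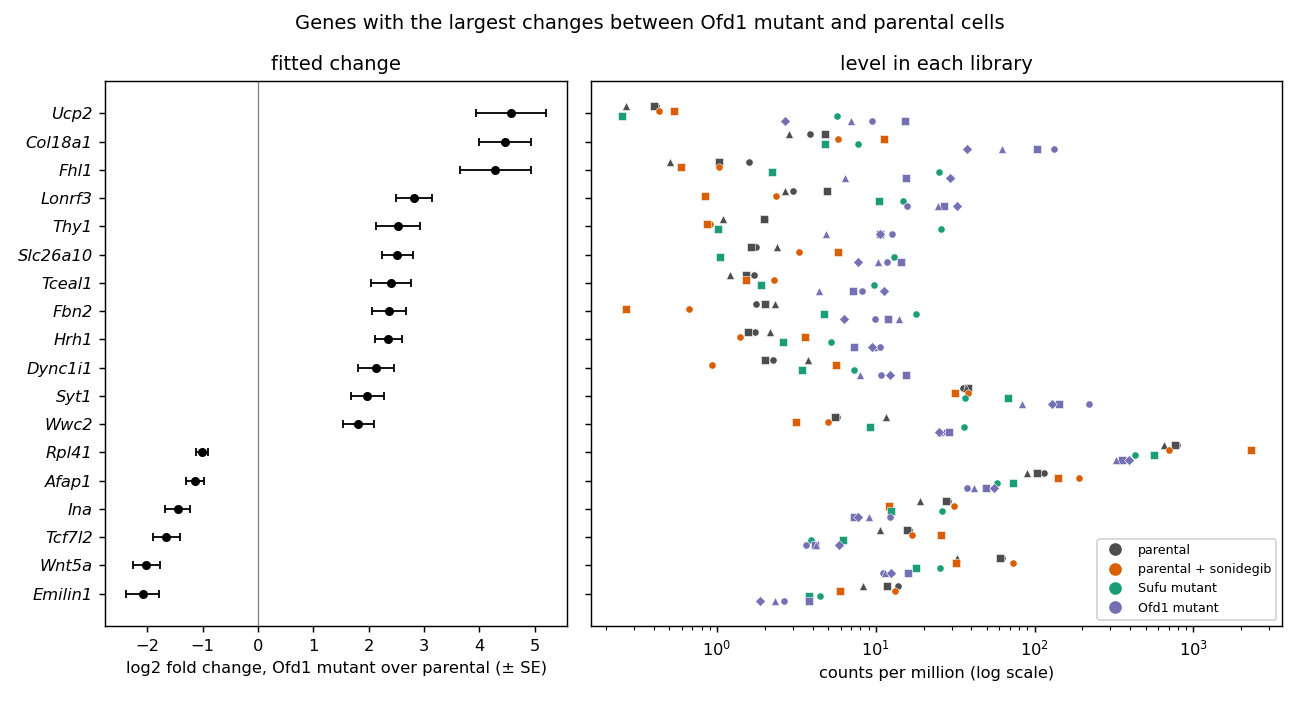
Log2 fold change with its SE for the genes named for Ofd1-mutant against parental cells (left) and their CPM (log axis) in each of the 11 libraries, coloured by group (right). The 4 Ofd1-mutant libraries lie apart from the 3 untreated parental libraries for each gene, as with Col18a1 at 37.8 or more against 4.75 or less.

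Hedgehog targets as a list did not change in the Ofd1 mutants. The 14 detected genes had a median of 0.06 and a mean of 0.12 while the camera test pointed downward (adjusted p = 0.826). Gli1 stood at 131 ± 48.3 against 229 ± 12.3 CPM, a log2 difference of -0.79 ± 0.27 with an adjusted p of 0.247. Over all genes 0 of the targets changed, and adjusted over the list alone 2 fell, Sfrp1 by -1.24 ± 0.35 and Cdk6 by -0.54 ± 0.12. Foxa2 at 2.53, Hhip at 0.62, Mycn at 0.47, Ccnd2 at 0.18, Ptch1 at 0.17, Ccnd1 at 0.06, Atoh1 at 0.05, Bcl2 at -0.06, Igf2 at -0.15 and Prdm1 at -0.25 did not pass. Foxa2 was at 1.93 without parental replicate 2 and 4.51 without parental replicate 3. The core of 4 (median 0.37, adjusted p = 0.826), the coreceptors (0.06, 0.483), other Hedgehog machinery (-0.09, 0.134) and S phase genes (0.06, 0.515) did not pass.

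Of the groups called in Ofd1 mutants, neural stem genes were lower (median -0.45, adjusted p = 5.35e-05), with Sox2 at 3.53 ± 2.39 against 30.0 ± 5.72 CPM, Sox1 at 81.5 ± 16.1 against 140 ± 4.98 CPM and 3 lower when adjusted over the list alone. MAPK output was higher (median 0.35, adjusted p = 0.00961), with Egr1 at 35.3 ± 9.32 against 14.4 ± 2.44 CPM and 6 higher over the list alone. Cilia genes were lower (median -0.07, adjusted p = 0.0205), and 10 of 74 lay below the parental libraries in every Ofd1 library, where chance separates 5.71% in either direction. These 10 include the mutated gene Ofd1, and the share of all genes so separated was not taken. By edgeR 1899 of all 13779 genes had an unadjusted p under 0.05. G2/M genes (median 0.14), cholesterol synthesis (0.21) and replication histones (0.45) were higher, each with an adjusted p of 0.0198. None of these passed with an estimated correlation (adjusted p = 0.661 to 0.830). The cilia call was lost without parental replicate 1 or 2 (adjusted p = 0.179 and 0.231), and the median was 0.11 with parental replicate 3 as the only control. With that control the MAPK and histone calls were also lost, at medians of 0.10 and 0.29. The medians of G2/M and cholesterol genes rose there to 0.39 and 0.54. S phase genes, not called with all 3 controls, had a median of 0.26 there, and Notch targets 0.42. With 1 control library no p is given for these. The MAPK and histone calls were lost without parental replicate 1 (0.0670 and 0.171), and the G2/M and cholesterol calls without parental replicate 3 (medians -0.00 and 0.06, adjusted p = 0.959 and 0.496). The G2/M call was also lost without R14 replicate 2, R16 or R25 (0.0793, 0.0812 and 0.168), the cholesterol call without R14 replicate 2 (0.283) or with the R14 libraries summed so that each clone counted once (median 0.096, 0.177), and the histone call without R25 (0.177).

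Markers of astrocytes (median -0.57, adjusted p = 0.132), oligodendrocytes (0.53, 0.178), microglia (0.24, 0.826), fibroblasts and pericytes (0.25, 0.271) and endothelium (0.47, 0.369) did not pass in the Ofd1 mutants. Granule progenitor genes (-0.01, 0.178), Wnt targets (-0.20, 0.178), stress response (0.09, 0.553), neuronal differentiation, TGF-beta and BMP, Notch, p53, hypoxia and glycolysis, interferon, matrix and drug efflux lists (adjusted p = 0.369 to 0.915) did not pass either.

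The count of 50 in the Ofd1 mutants depended on the libraries used. It was 1 with the R14 libraries summed so that each clone counted once, and 0 without parental replicate 1, parental replicate 2 or R14 replicate 2. It was 6 without R14 replicate 1, 11 without R16, 226 without R25 and 329 without parental replicate 3. With parental replicate 3 as the only control it was 0, with 1444 genes at an unadjusted p under 0.05. The DESeq2 test called 770, 442 higher and 328 lower, including all 50.

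Ofd1 against Sufu mutants compares the classes of clones with each other. Of 14026 genes, 1 changed, Trpm3, which codes for a calcium-permeable ion channel, at 19.2 ± 2.04 CPM (n = 4) in Ofd1 and 1.08 ± 0.167 CPM (n = 2) in Sufu mutants. The log2 difference was 4.12 ± 0.25 with an adjusted p of 0.00915. Parental replicates 1, 2 and 3 held 1.84, 2.26 and 10.3 CPM. At an unadjusted p under 0.05 there were 1253 genes, and the DESeq2 test called 266, 149 higher and 117 lower. The count was 11 without clone R13 and 2 without R1, neither of the 2 being Trpm3. It was 0 without either R14 library, without R16 or with the R14 libraries summed. With all 11 libraries in one fit 1 gene was called and it was not Trpm3, whose adjusted p was 0.327.

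The groups separated the clone classes by small amounts. Cholesterol synthesis was higher in Ofd1 than in Sufu mutants (median 0.48, adjusted p = 6.49e-12), with 23 of 24 genes positive, Hsd17b7 at 191 ± 27.4 against 97.0 ± 16.9 CPM and 5 higher when adjusted over the list alone. S phase (median 0.28, adjusted p = 1.42e-09), with the helicase subunit Mcm6 at 1274 ± 238 against 631 ± 49.0 CPM, and G2/M genes (0.23, 8.43e-07) were higher. Hedgehog targets (median -0.25, adjusted p = 0.0265), the core of 4 (-0.45, 0.0216), MAPK output (-0.19, 0.0262) and stress response genes (-0.49, 1.32e-04) were lower, and the last had a median of 0.18 without clone R1. None of these passed with an estimated correlation (adjusted p = 0.511 to 0.810). Among Hedgehog targets 0 changed over all genes and 1 fell over the list alone, Prdm1 by -1.92 ± 0.41. The Hedgehog call was lost without R13 (adjusted p = 0.592) or R14 replicate 1 (0.0541), the core call also without R1 (0.151), and the MAPK call without R13, R1 or R25 (0.110, 0.151 and 0.0564) or with all 11 libraries in one fit (0.0780). The other lists, including all other cell types, had adjusted p from 0.0799 for replication histones to 0.904. The plot of list medians sets these beside the comparisons with parental cells.

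**Figure D3:**
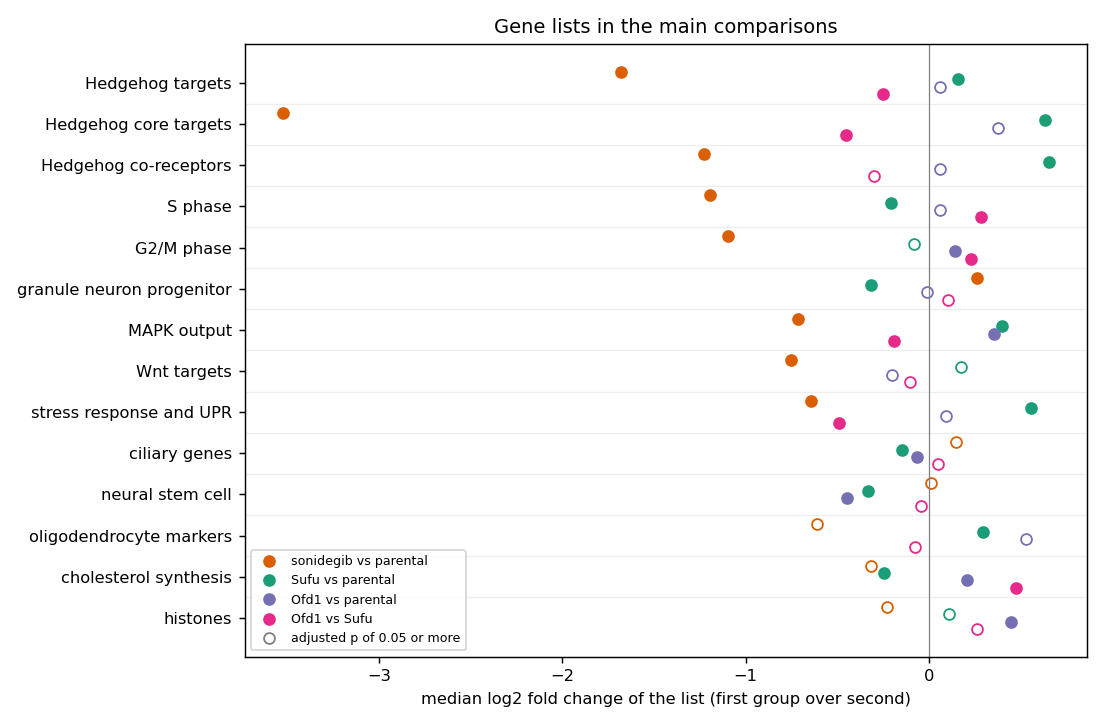
Median log2 fold change of 14 gene lists, first group over second, for sonidegib, Sufu and Ofd1 mutants against parental cells and for Ofd1 against Sufu mutants; open points had a camera adjusted p of 0.05 or more. S phase and G2/M genes have medians of -1.19 and -1.09 after sonidegib.

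Genes that fell with sonidegib, 8 in all, had a median of -0.43 in Ofd1 against Sufu mutants (p = 0.0226 by camera over genes with limma, and 0.128 with an estimated correlation). At the preset correlation it did not pass without clone R13, or without R14 replicate 1 (p = 0.0639 by camera). Lowered and raised genes were also taken inside the first set, where 1 sonidegib library leaves their membership unsure. With 453 genes defined inside the first set the median was 0.14 (p = 0.152 by camera, and 0.693 with an estimated correlation). The gene that rose with the drug, Igfbp5, had a log2 difference of 3.49 (2.71 without R25), at 121 ± 110 CPM in Ofd1 and 10.7 ± 2.69 CPM in Sufu mutants, and was not called by edgeR (adjusted p = 0.431). Untreated parental cells held 102 ± 13.3 CPM of Igfbp5. Both Sufu clones lay below every parental library, while Ofd1 libraries lay on both sides of them. The difference thus came mainly from low levels in the Sufu mutants. As a set of 1 gene Igfbp5 had p = 0.00608 by camera, and 0.0517 with an estimated correlation. Such a set tests only that gene, so nothing about a wider drug response is read from it. The 158 genes that rose inside the first set had a median of 0.29 (p = 1.14e-04, and 0.196 with an estimated correlation).

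Clones against sonidegib-treated cells show the same Hedgehog and cell cycle genes from the other side. The labels do not state whether the clones were grown with drug. These comparisons therefore cannot tell Hedgehog output kept in drug from the absence of drug. In Sufu mutants Gli1 was 4.85 ± 0.34 and Hhip 4.35 ± 0.38 higher on the log2 scale than in treated cells, and in Ofd1 mutants 4.01 ± 0.43 and 4.13 ± 0.64 higher. In Ofd1 mutants Ccnd1 and Bcl2 were also higher over all genes, by 1.74 and 1.26. Over the list alone, 7 targets were higher and 1, Atoh1, was lower in each clone class. The Hedgehog median was 1.66 for Sufu (adjusted p = 2.47e-14, and 0.227 with an estimated correlation) and 1.61 for Ofd1 mutants (3.17e-06, and 0.0853 with an estimated correlation). Over all genes 15 of 13613 changed for Sufu, 12 higher and 3 lower, and 900 of 14014 for Ofd1 mutants, 556 higher and 344 lower.

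In Ofd1 mutants 29 of 43 S phase and 32 of 52 G2/M genes were higher than in treated cells, with medians of 1.29 (adjusted p = 2.48e-34) and 1.28 (2.68e-30), Exo1 at 2.42, Atad2 at 2.19, Cenpf at 2.06 and Mki67 at 1.99. MAPK output was higher (0.95, 2.75e-07), with 7 genes higher and 1 lower, among them Etv4 at 3.87 and Dusp6 at 3.10. Cholesterol synthesis (0.38, 0.00259, 6 higher), stress response (0.76, 2.31e-04, 2 higher, with Slc7a5 at 2.53), the core of 4 (4.06, 2.33e-09), coreceptors (0.94, 0.00674, Cdon higher by 3.52) and replication histones (0.74, 0.0274) were higher. Granule progenitor (-0.78, 3.17e-06, 4 lower, with Barhl1 at -1.68), neural stem (-0.68, 0.00353, 5 lower, with Gfap at -3.04 and Vim at -1.91) and cilia genes (-0.24, 0.0112, 4 lower, with Foxj1 at -2.49) were lower. None of these passed with an estimated correlation (adjusted p = 0.0853 to 0.577). Without sonidegib replicate 1 the coreceptor, cilia, neural stem, cholesterol, stress and histone calls were lost (adjusted p = 0.122 to 0.846), and the histone call also without R25 (0.0799). The lists not called had adjusted p from 0.0555 for astrocyte markers to 0.944. Astrocyte markers had a median of -1.05, and their list shares Gfap and Slc1a3 with the neural stem list.

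In Sufu mutants the called lists were S phase (0.95, 6.52e-17), G2/M (1.02, 1.35e-17), the core of 4 (4.54, 8.59e-23), coreceptors (1.23, 0.00167), MAPK output (1.06, 9.39e-11, with Dusp6 higher by 3.46), Wnt targets (0.97, 0.00480) and stress response (1.21, 9.39e-11), all higher than in treated cells, and granule progenitor (-0.75, 7.37e-06) and cilia genes (-0.29, 0.0111), both lower. None passed with an estimated correlation (adjusted p = 0.227 to 0.539), and the coreceptor and cilia calls were lost without sonidegib replicate 1 (0.0673 and 0.265), the latter also without R1 (0.0581). The lists not called had adjusted p from 0.0560 for astrocyte and oligodendrocyte markers to 0.951. The count of 15 was 0 without either sonidegib library, 260 without R13 and 282 without R1. The count of 900 was 4806 without sonidegib replicate 1, 185 without replicate 2, 256 with the R14 libraries summed and 152 to 465 without each Ofd1 library in turn.

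Across 13648 genes, the fold changes of Ofd1 and Sufu mutants against the same parental cells had a Pearson correlation of 0.63 and a Spearman correlation of 0.52. Groups without a difference from the 3 shared controls gave a mean of 0.47 in 20 simulations. From differences of log CPM, the scale of the simulations, the covariance was 0.190, against 0.0651 simulated. The simulations drew libraries independently, without the sets that lay together on the second principal component. They therefore cannot tell an excess shared by the clone classes from a difference among the controls. Without parental replicate 3 the Pearson correlation was 0.75. Of DESeq2 calls, 61 genes were lower and 59 higher in both classes. Both sets of calls rest on the same parental libraries, so some sharing is built in. Sufu and sonidegib fold changes had a correlation of -0.10, against 0.39 simulated, and Ofd1 and sonidegib fold changes -0.01, against 0.48. Genes are not independent replicates, so no p is given, and these 3 correlations form the family computed.

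Median levels of whole chromosomes, examined after the data were seen, differed between single libraries. With length trends removed, 11 pairs of chromosome and library had a median shift of 0.2 or more in size on the log2 scale, in 6 libraries, while 95% of permutations stayed at or below 0.101 over all chromosomes and libraries. Chromosome 12 was higher by 0.38 and chromosome 9 by 0.22 in Sufu clone R1, and chromosome 15 changed by -0.22 in R13. Chromosome 4 was higher by 0.34 in Ofd1 clone R16, and chromosome 17 by 0.34 in R16, 0.29 in R14 replicate 2 and 0.21 in sonidegib replicate 2, with -0.06 in R14 replicate 1. Chromosome 8 was higher by 0.22 in R14 replicate 2, with 0.19 in R14 replicate 1, and changed by -0.25 in R25, which also had chromosome 14 at -0.22 and chromosome 1 at 0.22. In part 3 of 4 along chromosome 1, parental replicates 1 and 2 and sonidegib replicate 1 lay at 0.33, 0.38 and 0.29, and parental replicate 3 and sonidegib replicate 2 at -0.11 and -0.09.

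**Figure D4:**
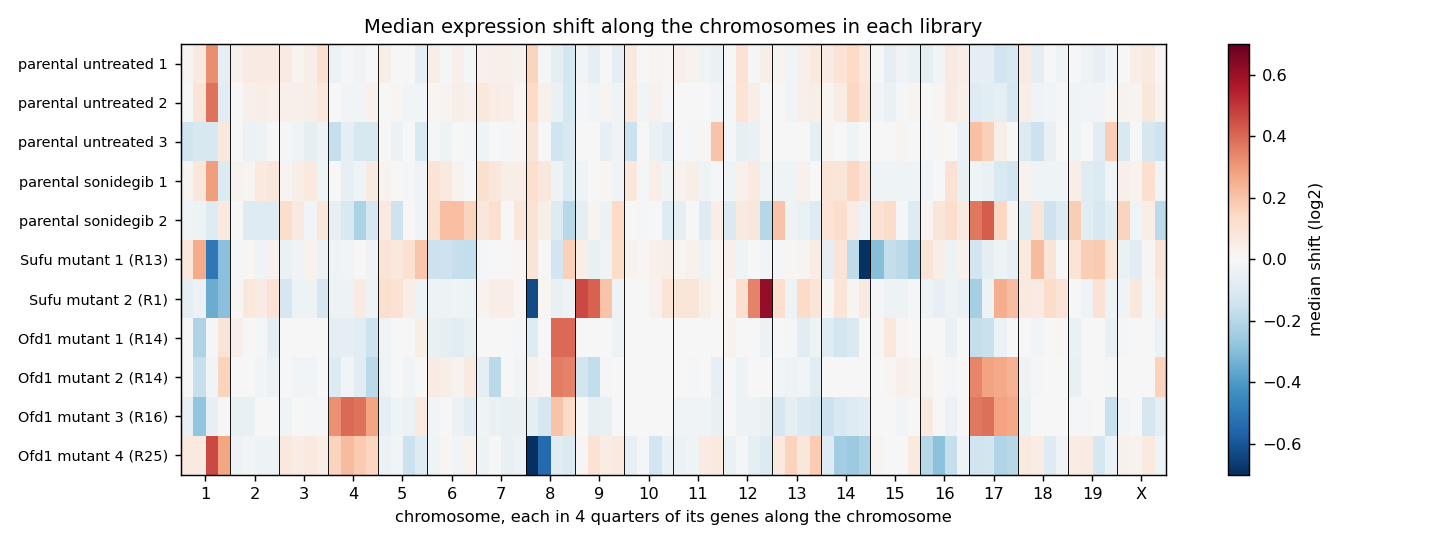
Median log2 shift of genes in each of 4 parts of each chromosome (columns) for each of the 11 libraries (rows), against the median of all libraries and with length trends removed; the colour scale ends at 0.7 in size. Chromosome 12 rises along its length to 0.62 in Sufu clone R1, and part 1 of chromosome 8 is at -0.70 in Ofd1 clone R25.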

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

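The tests of the second sonidegib library, of transcript length and drug exposure in parental replicate 3, of the distance of the Ofd1 libraries from that replicate, and of chromosomes on every second gene were chosen after the results were seen.

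In the Ofd1 mutants, Sfrp1, a secreted Wnt antagonist, stood apart in clone R16, at 301 CPM against 130 to 132 CPM in the other 3 libraries, a gap of 0.982 of the range. Cdk6, a kinase of the G1 phase, stood apart in clone R25, at 53.5 against 44.4 to 45.2 CPM, a gap of 0.911 of the range. Both pass the 95% limit of Dixon's test for 4 libraries. In all 35 genes were examined, and chance alone places about 1 in 20 past that limit. Trpm3 differed between the clone classes, with a log2 difference of 4.12 between Ofd1 and Sufu mutants, and no explanation of it was tested.

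The second sonidegib library lay apart from the first. Its difference from the first had a Spearman correlation with transcript length of -0.525, where no other pair of replicates exceeded 0.141 in size. Loss of long transcripts in that library may therefore be part of the difference. The S phase genes, 43 in all, had a median of -1.48 in the first library against parental replicates 1 and 2 and -0.97 in the second against parental replicate 3. The median paired difference, second minus first and with length trends removed, was 0.441. With 1 sonidegib library in each set the spread between libraries is not known, so a stronger drug response in that library cannot be told apart from a weaker one.

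Parental replicate 3 and the second sonidegib library differed alike from parental replicates 1 and 2 and the first sonidegib library. The correlation of these differences was 0.336 with length trends removed, which argues against loss of long transcripts as the whole cause, and 0.341 outside chromosome 17, which argues against that chromosome alone. Gli1 in parental replicate 3 was 1.09 times its mean in replicates 1 and 2, which argues against drug exposure of that culture. A difference in culture or in preparation, for which the labels give no batch, could underlie the pattern and was not tested.

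Chromosome medians shifted by 0.2 or more in 11 pairs of chromosome and library. Length trends are argued against, since 10 of 11 shifts stayed once these were removed. Pairs were also chosen on every second gene along a chromosome. Over the other genes, which took no part in the choice, every median was 0.178 or more in the direction of the shift, against a 95% limit of 0.158 for permuted chromosomes. The shifts were thus not confined to the genes that chose them. This cannot decide on a few strongly changed genes, since these hardly move a median and neighbouring genes share a shift of a region. All 4 parts of a chromosome shifted the same way by more than 0.1 in only 4 of 11 pairs, fewer than the planned test asked. Taken alone that went with a few strongly changed genes, but a shift of part of a chromosome also leaves parts unmoved. After the planned test 2 others were tried and set aside, since the choice of parts or pairs fixed their outcome. A change of chromosome copy number in the cells, whole or in part, stays open as a candidate explanation. The parts shared a sign in 10 of 11 pairs, but some by as little as 0.0071, and no DNA measurement was used here.

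Of the 35 splits of the Ofd1-mutant and parental libraries into 4 and 3, 2 gave 50 genes or more, the real one and 1 other, so chance is not excluded for the count of 50. That other split gave 103 genes. It set the R14 and R16 libraries against the parental libraries together with R25, and what this split reflects was not tested. The splits take the 2 libraries of clone R14 as separate samples. The difference of parental replicate 3 from replicates 1 and 2 stays open as a source of calls. Over the 329 genes called without replicate 3, which include all 50, the Ofd1 libraries lay a median of 0.54 (log2) from replicate 3 in the direction of the call. They lay 1.67 from replicates 1 and 2, on which those genes were chosen.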

How the results depend on the processing

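Removing length trends and the comparisons inside library sets were chosen after seeing the data. At these depths and with 2 to 4 libraries a group, 2-fold changes were mostly missed on simulated data outside Ofd1 against parental cells. Where a value below differs from the report, the cause was not tested, except that summing the R14 libraries and the library sets leave fewer libraries. Where a group is left with 1 library, it is assumed to vary like the other group. Counts of changed genes from such fits, those inside the library sets included, show dependence on the setting only. The sonidegib libraries differed by more than any parental pair (SD 1.01 against 0.376 to 0.752, log2). With DESeq2 size factors no count moved by more than 1.5 times.

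In the order sonidegib, Sufu and Ofd1 against parental cells, Ofd1 against Sufu, Sufu and Ofd1 against sonidegib, the DESeq2 Wald test changed 707, 324, 770, 266, 769 and 2536 genes. Without a filter on low counts the first 5 were 109, 3, 84, 2 and 164. With all 11 libraries in one fit, sonidegib gave 316, Ofd1 against parental cells 9, and Sufu and Ofd1 against sonidegib 1117 and 1965. With length-trend offsets, sonidegib gave 65, Sufu 2, Ofd1 92, and Sufu and Ofd1 against sonidegib 57 and 1377. With R14 libraries summed, Ofd1 gave 1 against parental cells, 0 against Sufu and 256 against sonidegib. A replicate block gave 97 for sonidegib, and 1583 for R14 and parental cells only, against 99 without the block. Within the first library set sonidegib gave 1393, and within the second Ofd1 gave 0 by edgeR, with 1444 at an unadjusted p under 0.05.

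Leaving out 1 library, the counts ran in the same order from 0 to 3263, 0 to 11, 0 to 329, 0 to 11, 0 to 282 and 152 to 4806. The Hedgehog target medians ran from -1.78 to -1.37, 0.068 to 0.24, -0.03 to 0.09, -0.47 to -0.14, 1.31 to 1.80 and 1.24 to 1.70. The sonidegib-lowered genes in Ofd1 against Sufu ran from -0.60 to -0.23. The fold change correlations ran from -0.081 to 0.045 for Sufu with sonidegib, 0.024 to 0.15 for Ofd1 with sonidegib and 0.62 to 0.75 for Ofd1 with Sufu.

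With an estimated correlation the Hedgehog target list no longer passed, at -1.68 for sonidegib, 0.16 for Sufu, -0.25 for Ofd1 against Sufu, and 1.66 and 1.61 for Sufu and Ofd1 against sonidegib. For Sufu it did not pass with all 11 libraries in one fit (0.21) or in the second set (0.14). The core list of 4 genes was at 0.37 for Ofd1. The sonidegib-lowered genes were at -0.43 with an estimated correlation, 0.14 with the set from the first library set, also with an estimated correlation, and 0.11 with that set without Hedgehog, S and G2/M genes. The 3 genes left of the 8 without those lists kept their call, at -1.11 (p = 5.93e-04 by camera at the preset correlation). At a mean of at least 10 CPM, Sufu and Ofd1 with sonidegib correlated at -0.22 and -0.11. Ofd1 with sonidegib was at 0.0056 with length-trend offsets, and Ofd1 with Sufu at 0.52 by Spearman.

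Of the lists called in the report, reversed medians were cilia at 0.038 and granule progenitor at 0.088 for Sufu and cilia at 0.11 for Ofd1 in the second set, and G2/M at -0.078 for Ofd1 with the replicate block. Stress response ran from -0.12 without Sufu replicate 2 to 0.95 for Sufu against parental cells, and from -0.82 to 0.18 without Sufu replicate 2 for Ofd1 against Sufu. The Sufu gene ran from -0.76 to 1.42 in Ofd1 against sonidegib, the latter without sonidegib replicate 1. Of the other values for named genes, 1230 kept direction and side of the threshold, 59 passed it newly and 199 no longer passed. For lists called in the report, 471 kept both and 110 no longer passed. Lists not called there passed newly 57 times, 56 of them in the same direction, the other being G2/M for Sufu in the second set. These counts include fits that leave 1 library in a group.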
